A study of Homo sapiens with 6 samples.

How the data were processed

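RNA from 6 cultures of C4-2 prostate cancer cells was measured, 2 each of vehicle-treated controls, cells given the DNA-PKcs inhibitor NU7441 (1 µM, 24 h) and cells transfected with an siRNA pool against PRKDC (96 h). Per the labels' protocols, RNA was extracted with Trizol, amplified to cDNA with a whole-transcriptome amplification kit, labelled with biotin and hybridised to Affymetrix Human Gene 2.0 ST arrays, after culture in medium with hormones. The values deposited by the authors are linear intensities, 1 per probeset and array. The summarisation, background correction, normalization and genome build are not given in the sources used here. No deposited intensity lay below 16, and the lowest values crowded just above it, as an added offset of 16 would give. If it is one, the fold changes of dim genes are understated, but a floor set in the summarisation would look alike and is not excluded. The arrays had similar upper percentiles and different medians, so they were not quantile normalized at the probeset level. Each array's column was tied to its sample by the sample's own identifier, and 0 columns belonged to no sample.

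The design fixed before the data were examined had assumed log2 values and foresaw a log2 transform of linear ones, which was applied with no further scaling. Gene names came from the platform annotation table given with the data, with the GRCh38.p14 gene table used to bring names up to date; all 15835 gene identifiers matched it and 0 symbols changed. No coordinates are given, since the build behind the probesets is not stated. Of 44629 probesets 15835 had 1 symbol, 0 had several and 28794 were unnamed here, and the unnamed ones were left out of the gene tests. The brightest probeset stood for each of the 651 genes with more than 1, leaving 14812 genes, of which 11911 are protein-coding in that table. No filter on dim genes was applied. PRKDC and several other genes of interest, including PREX1, ROCK2, ITGB4 and the UGT2B family, were not among the named probesets and are not analysed here.

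Differences were tested with limma 3.58.1 in R 4.3.3, with 1 linear model over all 6 arrays, 3 residual degrees of freedom, empirical Bayes moderation with a mean-variance trend, and Benjamini-Hochberg adjustment over all genes of a comparison, with a threshold of 0.05. All tests were two-sided. The comparisons were NU7441 against control, knockdown against control and knockdown against NU7441, the last of which tests the difference between the treatments directly. Values after ± are limma's moderated standard errors of log2 fold changes with n = 2 per group. Fitting on 2 arrays per group assumes that all groups share 1 spread. The median SD of log2 values was 0.087 for control, 0.139 for knockdown and 0.215 for NU7441. Standard errors may thus be too small in the NU7441 comparisons and too large for knockdown against control.

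The 28 gene lists, 21 of pathways, 6 of cell type markers and 1 of the study's own migration genes, were also fixed beforehand, and 27 with at least 3 measured genes were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. That minimum was set after the gene table was seen. Counts of list genes are out of the measured ones, and list members without a named probeset are not in them. The result of 1 pathway list is not reported here. Camera with an estimated correlation and fry stand beside it. With an estimated correlation, camera also uses the residual degrees of freedom (3 with all 6 arrays), so its p rises even where genes are uncorrelated. Camera compares a list with all other genes, and fry asks only whether its genes move one way. List medians were also set against 10000 random lists of the same size and matched mean intensity. The genes named were PRKDC, the 4 study migration genes, the 2 highest and 2 lowest members of each list against control, and, in each comparison, the 8 highest and 8 lowest fold changes among genes past the threshold. For the last part both arrays of a group had to lie on the same side of both arrays of the other, the higher group's mean had to exceed the median of tested genes, and entries for small RNAs, pseudogenes, LOC symbols and unnamed reading frames were left out. Not every list member that the rule allows is described. Genes chosen after their values were seen are stated as such.

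For the comparisons that share control arrays, 100 sets of unchanged groups were simulated against the same controls (20 for the overlap of calls), 100 more with the spread of the bright genes after quantile normalization, and the fold changes were recomputed with 1 control array for each treatment. Each simulated gene had 1 spread in all groups. The procedure was tested on simulated data for NU7441 against control, with 14812 genes, 200 of them changed, in 10 draws. It recovered 13.7% of genes changed 1.5-fold, 61.0% of those changed 2-fold and 98.3% of those changed 3-fold, with 7.95% of calls false, and called 10 of 10 lists of 20 genes shifted by −0.5 and 0 of the unshifted ones. Lists were counted there at an unadjusted camera p under 0.05. Genes were drawn independently with 1 spread for all groups, so false list calls among correlated genes were not tested. The real NU7441 arrays varied more than the others, and 4917 genes passed there. The recovery and the share of false calls, which already exceeded the threshold of 0.05, may therefore not hold for the real arrays.

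Alternatives fixed beforehand were a replicate block, leaving out each array, no mean-variance trend, a robust spread, quantile normalization, median centring, leaving out dim genes, the mean of a gene's probesets, the compared groups only, all probesets, other thresholds and other set tests. Taking 16 off every value with a floor of 16, and quantile normalization with dim genes left out, were added after the data were seen. No group held enough arrays for a test of single arrays standing apart or of other splits of the samples.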

Results

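RNA from C4-2 cells, a human prostate cancer line derived from LNCaP that grows without testicular androgens, was measured on 6 Affymetrix Human Gene ST arrays. The arrays fell into 3 groups of 2, which the labels call biological replicates: vehicle-treated controls, cells given NU7441 at 1 µM for 24 h, and cells depleted of DNA-PKcs with an siRNA pool against PRKDC for 96 h. NU7441 is a small molecule that blocks the ATP site of DNA-PKcs, the catalytic kinase of the DNA-PK complex, which joins broken DNA ends. The design asks which transcripts depend on DNA-PKcs activity or on the protein itself in these cells. Of 44629 probesets, 15835 carried 1 gene symbol here, which gave 14812 genes for testing. PRKDC was not among the named probesets, so the level of the depleted transcript was not analysed here, and the labels alone define the knockdown group.

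The arrays differed at the dim end of the scale. The median intensity over all probesets was 31.5 and 31.6 on the control arrays, 28.4 and 27.6 on the knockdown arrays, and 24.6 and 26.0 on the NU7441 arrays, whereas the 95th percentile lay between 289 and 299 on all 6. No value was below 16, and the number of probesets within 0.01 of that floor was 452 and 444 on the control arrays, 973 and 1206 on the knockdown arrays, and 3797 and 1471 on the NU7441 arrays. The Pearson correlation between the 2 arrays of a group, across probesets on the log2 scale, was 0.988 for control, 0.970 for knockdown and 0.937 for NU7441. The number of arrays limits the precision, with a median standard error of 0.22 for a log2 fold change.

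**Figure D1:**
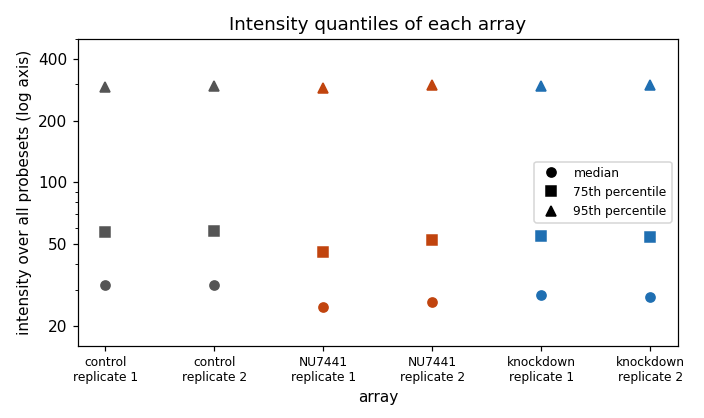
Median, 75th and 95th percentile of intensity over all 44629 probesets (y axis, log scale) for each of the 6 arrays (x axis). The 95th percentiles lie between 289 and 299, and the medians run from 24.6 on NU7441 replicate 1 to 31.6 on control replicate 2.

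NU7441 against control addressed the response to kinase inhibition. In NU7441-treated cells the transcripts of dividing cells fell together: all 21 measured genes of the mitosis list and 19 of the 20 DNA replication genes were lower, while 12 of 16 cholesterol synthesis genes were higher. MAD2L1, a spindle checkpoint protein, fell 8.19-fold (log2 fold change −3.03 ± 0.43, SE, n = 2 per group), and SMC2, a condensin subunit, fell 7.76-fold (−2.96 ± 0.29). SOX2, a transcription factor of stem and neural cells, fell 7.26-fold (−2.86 ± 0.19), from a mean intensity of 665 to 93.3. TM7SF2, a sterol reductase of cholesterol synthesis, rose 4.07-fold (2.03 ± 0.21), and TP53INP1, a stress protein induced by p53, rose 3.72-fold (1.90 ± 0.13). In all, 4917 genes passed the threshold of limma's moderated test with Benjamini-Hochberg adjustment, 1605 higher and 3312 lower.

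The remaining genes with the lowest fold changes were ZNF830 (−3.17 ± 0.33), PRAMEF22 (−2.94 ± 0.25), HOXD1 (−2.87 ± 0.25), PSAPL1 (−2.83 ± 0.33) and CBLN1 (−2.83 ± 0.15). PRAMEF22 belongs to a family of near-identical genes, so its probes may not tell the copies apart. HOXD1 and PRAMEF22 were near the floor in treated cells, at mean intensities of 22.8 and 21.3 against 164 and 165 in controls. On the higher side were SYCE3, a synaptonemal complex protein (1.93 ± 0.16), PCMTD1 (1.78 ± 0.13), GRN, which encodes progranulin (1.76 ± 0.22), CFAP69 (1.73 ± 0.22), GRB10, an adaptor that dampens insulin receptor signalling (1.72 ± 0.20), and CNFN (1.71 ± 0.20). Adjusted p for the 16 genes ranged from 2.8e-05 for CBLN1 to 0.00169 for MAD2L1. For each gene both NU7441 arrays lay on the same side of both control arrays, as the rule for naming genes required.

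**Figure D2:**
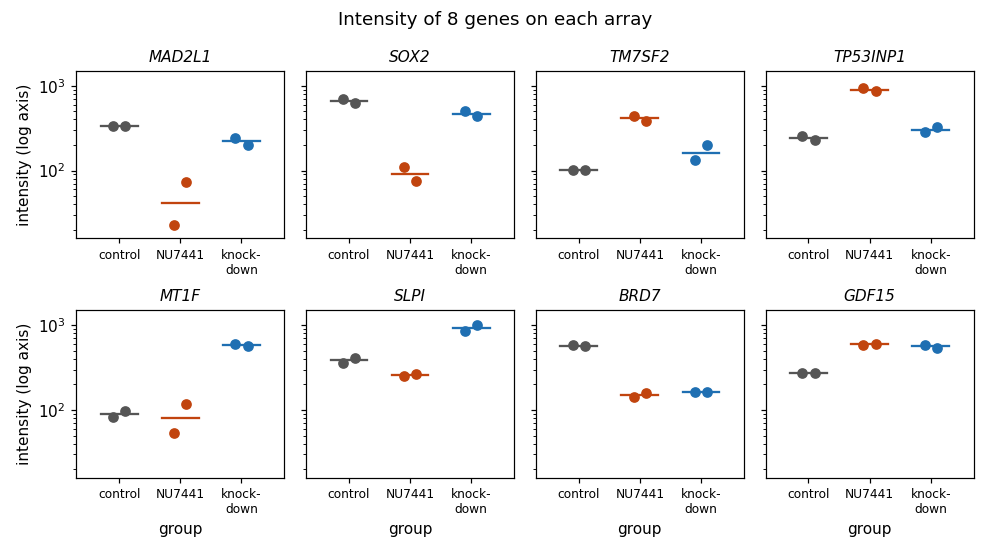
Intensity (y axis, log scale) of 8 genes on each of the 6 arrays, by group (x axis), with points for arrays and lines for the mean of the log2 values. SOX2 averages 665 in control, 93.3 under NU7441 and 467 after knockdown, and BRD7 averages 573, 150 and 161.

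The median log2 fold change of all tested genes was −0.23 in this comparison, and quantile normalization brought it to 0.01, so list medians are given relative to all genes. The shift varied with brightness: the median was −0.29 at mean log2 values of 4 to 5 and 0.21 above 8. After knockdown these medians were −0.17 and 0.11. Values relative to all genes do not remove that part of the shift, which the random lists of matched intensity allow for. The median of the mitosis list was −1.53 relative to all genes (camera adjusted p = 3.18e-13, 0.243 as the adjusted p with an estimated correlation), with KIF20A at −2.41 ± 0.29, TOP2A at −2.26 ± 0.26, CDK1 at −1.01 ± 0.13 and BIRC5 at −0.70 ± 0.16. DNA replication and E2F target genes lay at −0.85 relative to all genes (adjusted p = 1.53e-08, and adjusted p = 0.290 with an estimated correlation), led by CCNE2, a G1/S cyclin (−2.01 ± 0.39), and GINS1 of the replicative helicase (−1.91 ± 0.28). CCNE1, the member that did not pass, was at −0.73 ± 0.26. It passed without the trend, with dim genes left out and without NU7441 replicate 2. Of 15 homologous recombination genes 11 fell, among them RAD51AP1 (−2.51 ± 0.33) and EXO1 (−2.24 ± 0.34), and the list lay at −0.93 relative to all genes (adjusted p = 0.00449, and adjusted p = 0.387 with an estimated correlation). Of 8 end-joining genes 5 fell, including XRCC5, the Ku80 subunit of DNA-PK (−1.43 ± 0.14), and RIF1 (−1.34 ± 0.25), with the list at −0.71 (adjusted p = 0.0153, and adjusted p = 0.387 with an estimated correlation). XRCC6, the Ku70 subunit, was at −0.21 ± 0.08 with an adjusted p of 0.0718, and at 0.11 with median centring. It passed after quantile normalization (−0.28, adjusted p = 0.0279) and with dim genes left out. Adjusted over the list alone, 21 mitosis, 20 replication, 11 recombination and 7 end-joining genes were lower and none was higher.

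Most genes of the list of MYC targets and ribosome biogenesis fell, whereas MYC itself, a member of the list, rose. Of its 15 measured genes 11 were lower, including NOP16 (−1.49 ± 0.18) and NOP58 (−1.35 ± 0.13), and MYC was 1.12 ± 0.14 higher. The list lay at −0.46 relative to all genes (camera adjusted p = 7.64e-04, and adjusted p = 0.243 with an estimated correlation). The glucuronidation and steroid inactivation list was called lower (−0.65, adjusted p = 0.0342, and adjusted p = 0.425 with an estimated correlation), and its 5 measured genes all fell. These were UGP2 (−1.33 ± 0.29), HSD17B6 (−1.21 ± 0.39), UGDH, HSD17B4 (−0.74 ± 0.21) and HSD17B2 (−0.61 ± 0.18, near the floor on every array), enzymes of UDP-sugar supply and of steroid and fatty acid oxidation, with no UDP-glucuronosyltransferase among them. UGDH is named beyond the fixed rule, after its value was seen (−0.88 ± 0.15). After quantile normalization 4 of the list's 5 genes were lower past the threshold. That list's call was lost without NU7441 replicate 1, without either knockdown replicate, without the mean-variance trend, with the compared groups alone and with the offset taken off (adjusted p from 0.00706 to 0.107 over the alternatives). Adjusted over the list alone, 12 MYC target genes were lower and 1 higher, and all 5 glucuronidation genes were lower.

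More genes of lipid synthesis and of FOXO control rose than fell. Of the 16 cholesterol genes 12 were higher and 1, EBP (−0.54 ± 0.11), was lower, with TM7SF2 and DHCR7 (1.17 ± 0.16), both sterol reductases, the most raised (list at 1.01 relative to all genes, adjusted p = 1.30e-07, and adjusted p = 0.241 with an estimated correlation). Of 15 fatty acid genes 8 rose, including FASN, the fatty acid synthase (1.11 ± 0.14), and SCD, the stearoyl-CoA desaturase (0.91 ± 0.10), with the list at 0.71 (adjusted p = 1.06e-04, and adjusted p = 0.290 with an estimated correlation). Of 19 FOXO and insulin signalling genes 10 rose and 1 fell. KLHL24 (1.17 ± 0.22) and IRS2 (1.03 ± 0.29) were the highest, IRS1, an insulin receptor substrate, fell (−1.21 ± 0.22), and the list lay at 0.96 (adjusted p = 4.24e-04, and adjusted p = 0.243 with an estimated correlation). Adjusted over the list alone, 12 cholesterol, 9 fatty acid and 11 FOXO genes were higher, and 1, 0 and 1 lower.

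The p53 target list was called higher (0.56 relative to all genes, adjusted p = 0.0220, and adjusted p = 0.290 with an estimated correlation), with members on both sides. TP53INP1 and SESN1 (1.26 ± 0.17) were among 5 that rose, and BAX, a pro-apoptotic protein (−1.07 ± 0.26), and SPATA18 (−1.35 ± 0.26) among 3 that fell; the call was lost with median centring and with the offset taken off (adjusted p from 0.0106 to 0.109 over the alternatives). Of 15 glycolysis and hypoxia genes 7 rose and 1 fell, with KDM3A (1.22 ± 0.20) and ANKRD37 (1.01 ± 0.24) highest and PGAM1 (−0.70 ± 0.11) lowest. That list lay at 0.56 (adjusted p = 0.00383, and adjusted p = 0.387 with an estimated correlation), and 1404 of 10000 random lists of matched intensity had a median as high (at most 235 as extreme for each of the other 10 called lists), and its call was lost after quantile normalization with dim genes left out (adjusted p = 0.101). The p53 and glycolysis counts adjusted over the list alone were the same as over all genes.

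The androgen response list was not called (adjusted p = 0.203), with 5 genes higher and 4 lower of 18, or 6 and 5 adjusted over the list alone. KLK4 (1.35 ± 0.14) and HERC3 (1.04 ± 0.16) rose, EAF2 (−1.63 ± 0.29) and SGK1 (−0.98 ± 0.23) fell, and KLK3, which encodes prostate-specific antigen, rose by 0.51 ± 0.12. VAV3, a guanine nucleotide exchange factor, fell (−2.52 ± 0.26). VAV3 is the 1 gene named here of the 4 migration genes that the study followed up from these arrays, so its fall is not independent evidence. Of the 3 measured PI3K-like kinase genes MTOR (0.63 ± 0.16) and TRRAP (0.83 ± 0.18) rose, with the list not called (adjusted p = 0.0941).

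The other 7 pathway lists described here were not called, with 2 higher and 3 lower of 20 interferon, 0 and 3 of 14 NF-kB, 2 and 4 of 15 unfolded protein response, 3 and 2 of 19 immediate early, 1 and 1 of 15 Wnt, 2 and 4 of 15 mesenchymal, and 7 and 5 of 20 epithelial genes. Quantile normalization changed these counts, in the same order, to 3 and 3, 1 and 2, 3 and 4, 4 and 0, 1 and 0, 2 and 3, and 7 and 3. IRF7 (1.17 ± 0.24), JUNB (1.24 ± 0.22) and JUP (0.98 ± 0.18) were the highest in their lists, and NFKB2 (−1.58 ± 0.24), ZEB2 (−1.56 ± 0.26) and DSG2 (−1.30 ± 0.27) the lowest in theirs. Among markers of other cell types, 4 of 10 neuroendocrine genes were lower, with SOX2 and CHGB (−0.88 ± 0.24) lowest (list adjusted p = 0.0544), 2 of 5 stromal genes, 3 of 9 endothelial genes and 1 of 6 basal genes were lower, and 0 of 7 leukocyte genes passed limma's test (1 lower at an unadjusted p under 0.05). With quantile normalization 2 stromal, 2 endothelial and 1 basal gene were lower, and 1 basal and 1 leukocyte gene were higher. After quantile normalization 1 of the 10 neuroendocrine genes was lower, and CHGB lost its call there, with median centring, with the offset taken off, and without either control replicate or NU7441 replicate 1. Counts adjusted over the list alone became 3 higher for unfolded protein, 0 for Wnt, 8 lower for mesenchymal, 7 lower for epithelial and 5 lower for neuroendocrine genes. None of these 5 marker groups was called, and 1 of 7 luminal genes, KLK3, was higher. The median and the mean lay on opposite sides of 0 for the androgen response, unfolded protein and immediate early lists, none of which was called.

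**Figure D3:**
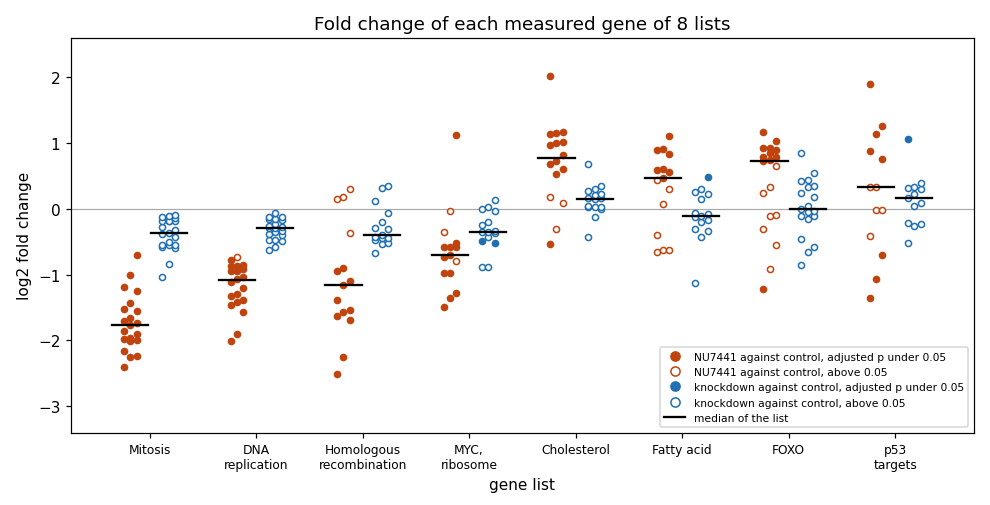
Log2 fold change against control (y axis) of each measured gene of 8 lists (x axis), for NU7441 (orange) and knockdown (blue), filled where the adjusted p was under 0.05, with black lines at list medians. All 21 mitosis genes are filled and below 0 for NU7441, and 0 of 21 are filled for the knockdown.

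The excess of lower genes under NU7441 depended on scaling: 67.4% of the called genes were lower as deposited, 49.0% after quantile normalization (2117 higher, 2037 lower) and 33.0% after median centring (2927 higher, 1441 lower). Without control replicate 1 or 2 the count was 1051 and 868, and without NU7441 replicate 2 it was 7845, with 1 array left to stand for its group. Of the 78 genes named here that passed, 21 and 30 lost the call without control replicate 1 or 2.

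Knockdown against control addressed loss of the protein. In DNA-PKcs-depleted cells MT1F, a metal-binding metallothionein, rose 6.53-fold (2.71 ± 0.31, n = 2 per group) and BRD7, a bromodomain subunit of a SWI/SNF chromatin remodelling complex, fell 3.55-fold (−1.83 ± 0.15), from a mean intensity of 573 to 161. SLPI, a secreted protease inhibitor, rose 2.43-fold (1.28 ± 0.13), and GDF15, a stress-induced cytokine and p53 target, rose 2.08-fold (1.06 ± 0.11). In all 114 genes passed the threshold, 42 higher and 72 lower, and camera called the mitosis, DNA replication and MYC target lists lower, each call being lost with an estimated correlation (adjusted p = 0.425). Further genes that rose were TARP (1.46 ± 0.21), GSTA1, a glutathione transferase (1.40 ± 0.20), S100P, a calcium-binding protein (1.26 ± 0.20), FOXD4L6 (1.25 ± 0.17) and ETFRF1 (0.95 ± 0.16). Further genes that fell were PRAMEF22 (−2.38 ± 0.25), PRAMEF5 (−2.00 ± 0.27), PNMA8B (−1.81 ± 0.25), STAC (−1.66 ± 0.27), CAPN6 (−1.66 ± 0.26), NRROS (−1.55 ± 0.29) and MCCD1 (−1.46 ± 0.22). MT1F, TARP, GSTA1, FOXD4L6 and the PRAMEF genes belong to families of similar sequence, so their probes may read related copies. Adjusted p for the 16 genes ranged from 0.00183 for BRD7 to 0.0498 for NRROS. The naming rule required both knockdown arrays on the same side of both control arrays for each.

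The mitosis list lay at −0.27 relative to all genes (camera adjusted p = 0.00182, and adjusted p = 0.425 with an estimated correlation), with 0 of 21 genes past limma's threshold singly, 8 lower at an unadjusted p under 0.05, and 2 lower adjusted over the list alone. NUSAP1, a spindle-associated protein, was at −1.03 ± 0.22 and KIF20A at −0.84 ± 0.29, with adjusted p of 0.0682 and 0.164. DNA replication genes lay at −0.20 (adjusted p = 0.00844, and adjusted p = 0.425 with an estimated correlation), with 0 of 20 past the threshold, 5 lower at an unadjusted p under 0.05, and 1 lower adjusted over the list alone. Of 15 MYC target genes 2 fell, NCL (−0.49 ± 0.09) and FBL (−0.51 ± 0.09), both nucleolar proteins of ribosome assembly that are named beyond the fixed rule, after their values were seen. The MYC target list lay at −0.27 (adjusted p = 0.00681, and adjusted p = 0.425 with an estimated correlation), and 6 of its genes were lower adjusted over the list alone.

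Lists called higher were the androgen response (0.20 relative to all genes, adjusted p = 0.00681), glycolysis and hypoxia (0.23, adjusted p = 0.00844), and unfolded protein and amino acid stress (0.38, adjusted p = 0.0193) genes, each with an adjusted p of 0.425 with an estimated correlation. In the first 2 no gene passed over all genes tested, while at an unadjusted p under 0.05 the androgen response had 6 genes higher and the glycolysis list 5 higher and 1 lower. Adjusted over the list alone, 2 of 18 androgen response genes were higher, as were 4 of 15 glycolysis genes, and 1 glycolysis gene was lower. NDRG1, on both lists, was at 0.91 ± 0.18 and ANKRD37 at 1.18 ± 0.24, with adjusted p of 0.0569 and 0.0572. ASNS, the asparagine synthetase, was the 1 stress gene of 15 that rose (0.79 ± 0.10), and adjusted over the list alone it rose while ATF4 (−0.48 ± 0.10) fell. Random lists of matched intensity had medians as high in 2374 of 10000 draws for the androgen response, 2171 for glycolysis and 136 for the stress list. After quantile normalization these counts were 774, 3871 and 259. Medians were as low in 0 for mitosis, 12 for replication and 5 for the MYC targets, and in 1, 26 and 5 after quantile normalization. All 3 calls were lost when dim genes were left out, the stress call also after quantile normalization, and the glycolysis and stress calls without knockdown replicate 1 and with the offset taken off.

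The other 21 tested lists were not called, and the interferon list had a median above 0 and a mean below it. Of these, the end-joining list (−0.34 relative to all genes, adjusted p = 0.0648) and the recombination list (−0.30, adjusted p = 0.212) were called lower after quantile normalization (0.0186 and 0.0218) and with the compared groups alone (0.0447 for both). With an estimated correlation these calls were lost (adjusted p = 0.415 and 0.520 after quantile normalization, and adjusted p = 0.484 for both with the compared groups alone). Medians as low came up in 35 and 5 of 10000 random lists of matched intensity, and as high in 118 for interferon and 317 for Wnt. In fatty acid synthesis ELOVL5, a fatty acid elongase, rose (0.49 ± 0.08), and of 13 p53 targets GDF15 alone passed the test. None of the 3 PI3K-like kinase, 8 end-joining, 15 recombination, 16 cholesterol, 5 glucuronidation, 19 FOXO, 20 interferon, 14 NF-kB, 19 immediate early, 15 Wnt, 15 mesenchymal or 20 epithelial genes passed with all 6 arrays in the fit, and none of the luminal, basal, neuroendocrine, stromal, leukocyte or endothelial markers. At an unadjusted p under 0.05 the epithelial list had the most, 4 higher and 3 lower, and adjusted over the list alone the interferon list had 2 higher and 2 lower. VAV3 was at −1.29 ± 0.26 with an adjusted p of 0.0579 over all genes. It passed after quantile normalization, with the compared groups alone (adjusted p = 3.09e-04) and without either NU7441 replicate. Without control replicate 2 its adjusted p was 0.495.

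The protocol mentions a control siRNA pool, but the labels describe the control arrays as vehicle-treated and do not say whether they received it, so transfection and depletion are not separated. The count of 114 came from a spread shared with the NU7441 arrays: with the control and knockdown arrays alone it was 2843 (1021 higher, 1822 lower). Of the lists called, 12 mitosis, 9 replication and 7 MYC target genes were then lower and none higher. The androgen response had 6 higher and 1 lower, glycolysis 5 and 1, and the stress list 6 and 2. Of the lists not called, 4 of 8 end-joining and 5 of 15 recombination genes were lower and none higher. The counts were 2 higher and 4 lower for interferon, 3 and 3 for FOXO, 4 and 5 for epithelial, 1 and 3 for fatty acid, and 1 and 1 for cholesterol genes. They were 1 and 2 for NF-kB, 2 and 2 for immediate early, 2 and 0 for Wnt, 1 and 2 for mesenchymal, 1 and 0 for p53 and 0 and 1 for glucuronidation genes. Among the markers, 3 endothelial, 2 basal, 2 neuroendocrine and 1 luminal genes were lower and 1 luminal gene was higher. NUSAP1, KIF20A, NDRG1, ANKRD37 and ATF4 also passed there, and all but KIF20A after quantile normalization. Without NU7441 replicate 1 or 2 the total was 2884 and 2855, without control replicate 1 or 2 it was 2 each, and without knockdown replicate 1 or 2 it was 3 and 1, where 24, 24, 24 and 25 of the 26 genes named here that had passed lost the call. Median centring turned the split to 81 higher and 27 lower.

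Setting knockdown directly against NU7441 asked where the treatments differed, at 96 h and 24 h respectively. Most mitosis and replication genes were higher after knockdown than under NU7441, with 20 of 21 mitosis, 14 of 20 replication and 7 of 15 recombination genes past the threshold and none lower. MAD2L1 was 5.39-fold higher after knockdown (2.43 ± 0.43) and PBK, a mitotic kinase, 5.13-fold higher (2.36 ± 0.28), while TP53INP1 was 2.97-fold lower (−1.57 ± 0.13). In all 1284 genes passed, 863 higher and 421 lower after knockdown. MT1F (2.88 ± 0.31), PARPBP (2.64 ± 0.37), EAF2 (2.48 ± 0.29), TEX30 (2.44 ± 0.56), CBLN1 (2.35 ± 0.15) and SOX2 (2.35 ± 0.19) were the other genes highest after knockdown. LRRN1 (−2.14 ± 0.24), YPEL2 (−1.60 ± 0.29), ACKR3, a chemokine-scavenging receptor (−1.55 ± 0.14), SYCE3 (−1.51 ± 0.16), NUDT14 (−1.50 ± 0.22), DOCK9, an activator of Cdc42 (−1.49 ± 0.20), and MMP16 (−1.45 ± 0.14) were the others lowest. Adjusted p for these 16 ranged from 2.47e-04 for CBLN1 to 0.0309 for TEX30.

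Relative to all genes, the mitosis list lay 1.22 higher after knockdown (adjusted p = 2.53e-18, and adjusted p = 0.211 with an estimated correlation), the replication list 0.67 higher (3.78e-10, and adjusted p = 0.265 with an estimated correlation), and the recombination list 0.60 higher (9.91e-04, and adjusted p = 0.421 with an estimated correlation). The MYC target list was 0.38 higher (adjusted p = 0.00981, and adjusted p = 0.265 with an estimated correlation), with 5 genes higher and MYC lower. The glucuronidation list was 0.56 higher (adjusted p = 0.0430, and adjusted p = 0.545 with an estimated correlation), with 2 of 5 genes higher. Cholesterol genes were 0.84 lower after knockdown (adjusted p = 1.56e-08, and adjusted p = 0.203 with an estimated correlation), with 9 of 16 lower, and fatty acid genes 0.61 lower (1.09e-05, and adjusted p = 0.265 with an estimated correlation), with 6 of 15 lower and ELOVL5 higher. FOXO genes were 0.55 lower (4.13e-04, and adjusted p = 0.211 with an estimated correlation), with 6 of 19 lower and 2 higher. The other 19 tested lists were not called, and in the immediate early, luminal and basal lists the median lay above 0 and the mean below it. Adjusted over the list alone, 21 mitosis, 19 replication, 9 recombination, 7 MYC target and 4 glucuronidation genes were higher, and 11 cholesterol, 9 fatty acid and 9 FOXO genes lower, with 1 MYC target lower, 2 fatty acid genes higher and 3 FOXO genes higher. The glucuronidation call was lost without NU7441 replicate 1, without either knockdown replicate, without the trend, with dim genes left out and with the offset taken off (adjusted p from 0.0105 to 0.191 over the alternatives), and the MYC target call without NU7441 replicate 2, without the trend and with median centring (from 4.47e-04 to 0.194).

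The duration and the means of inhibition differ between these groups, so no part of a difference is assigned to either. Leaving out 1 array moved the count widely: it was 416 and 421 without control replicate 1 or 2, 2578 and 5101 without NU7441 replicate 1 or 2, and 7 and 0 without knockdown replicate 1 or 2 (limma, against 4153 genes at an unadjusted p under 0.05 with all arrays), and 17 and 18 of the 18 genes named here lost the call without those knockdown arrays. The split was 591 higher and 946 lower with median centring, and 796 and 618 after quantile normalization.

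The last comparison asked how far the responses ran together. Of the 42 genes that rose after knockdown 30 also rose under NU7441, among them GDF15, FOXD4L6 and ETFRF1, and of the 72 that fell 68 also fell, among them BRD7, PRAMEF22 and STAC. Independent lists of these sizes would share 4.55 and 16.1 genes, and unchanged groups simulated against the same controls, which leave out the effects and so give few calls, shared at most 1. With 2 control arrays the overlap could not be split by control, so part of its excess may come from the shared controls. Opposite calls numbered 3 and 1: SLPI, MT1X and TTR rose after knockdown and fell under NU7441, and MYO6 fell and rose, MT1X, TTR and MYO6 being named after their values were seen. MT1F, TARP, GSTA1 and S100P did not pass under NU7441. Across 14812 genes, which are not independent replicates, the fold changes correlated with Pearson's r of 0.649 and a Spearman coefficient of 0.652, against a mean r of 0.498 in 100 simulations of unchanged groups with the shared controls. The sign matched for 75.7% of genes and 66.6% in the simulations. These gave all groups 1 spread per gene, whereas the median SD of log2 values was 0.087 for control, 0.139 for knockdown and 0.215 for NU7441. The simulated r, sign match and covariance depend on that assumption. Control arrays varied least, and a smaller control spread lowers each of these simulated values, so they may be too high. The covariance was 0.150 against 0.0280, a difference of 0.122. With separate control arrays for the 2 treatments r was 0.566 and 0.600, each treatment then having 1 control array of its own. The 98 shared calls became 1982 and 2174 without NU7441 replicate 1 or 2, 2 and 2 without control replicate 1 or 2, and 2 and 1 without knockdown replicate 1 or 2.

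**Figure D4:**
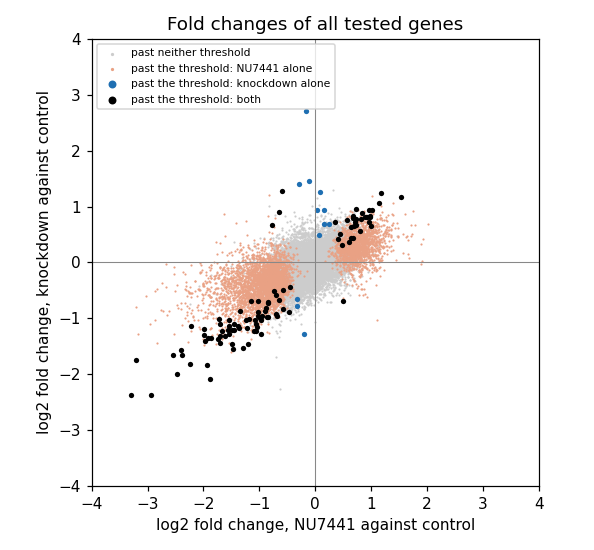
Log2 fold change of each of the 14812 tested genes under NU7441 (x axis) and after knockdown (y axis), both against the same 2 control arrays. Black points mark the 102 genes past the threshold in both comparisons, of which 98 lie in the lower left and upper right quadrants, and r over all genes is 0.649.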

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

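The tests of the excess of lower genes and the covariance test among bright genes were chosen after the results were seen; the other tests of the cell-cycle and correlation patterns were set beforehand.

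Probesets without a gene name here, which no comparison of genes uses, also passed limma's threshold. Of 28794 such probesets, 4880 passed for NU7441 against control (1045 higher, 3835 lower), 171 for knockdown against control (42 higher, 129 lower) and 702 for knockdown against NU7441 (516 higher, 186 lower).

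Of the genes called under NU7441 67.4% were lower. A difference in the arrays' scale at the dim end may account for the excess, since quantile normalization brought the lower share to 49.0%, although it would also level a true global fall. NU7441 replicate 1, the array with the most probesets near the floor, was argued against as the whole source, because the share was 61.4% without it. Whether NU7441 also lowered total RNA is open, since an array of equal RNA input cannot show it.

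The mitosis and replication genes were lower under NU7441, and a scale difference at the dim end was argued against: 0 of 10000 random lists of matched intensity had a median as low as either list, as deposited or after quantile normalization. A single deviant array was argued against too. After quantile normalization the combined median of both lists was −1.29 on the NU7441 array nearer to 0 and −1.45 on the other. Fewer cycling cells under kinase inhibition is one biological hypothesis that the values would be consistent with, and cell number and cell-cycle phase were not measured here. The camera calls assume a small correlation between genes and were lost with an estimated one. That loss does not by itself show that genes were correlated, since the estimated setting also leaves camera few degrees of freedom. For the p53 list after knockdown with quantile normalization, the estimate was −0.023, yet camera's unadjusted p rose from 0.0316 to 0.107. After knockdown, with the compared groups alone, the end-joining and recombination calls were lost at estimates of −0.123 and −0.068, below the preset 0.01.

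The fold changes of knockdown and NU7441 correlated across genes. Shared controls were argued against as the whole cause, because the covariance was 5.00 times the highest simulated one. The dim-end scale was argued against because the covariance among 3002 bright genes after quantile normalization was 11.4 times the highest simulated there. Their r was 0.703 against at most 0.547 for unchanged groups simulated with 1 spread for all groups. The bound of 0.5 set beforehand lay within that simulated r, so it was too low on that assumption. The 56 genes of the cell-cycle lists are too few to carry the correlation (r of 0.650 without them, and 0.636 without the 56 genes with the largest products of fold changes), and a wider cell-cycle response outside the lists stays open. A response shared through DNA-PKcs may remain as a hypothesis, and so may handling common to both treatments and absent from the controls, which no value here tests.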

How the results depend on the processing

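The setting that takes off an apparent offset of 16 and the joint setting of quantile normalization without dim genes were chosen after the data were seen. With 2 arrays per group, counts of genes depended on the arrays and on the estimate of spread, and directions of named genes less so; where no cause is given, the cause was not tested. The spread in the 4 arrays of control and knockdown was smaller than that in the NU7441 arrays, and leaving the latter out raised the knockdown count.

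For knockdown against control, the 114 genes became 4 without the trend, 199 with quantile normalization, 2843 with the compared groups only, 530 with the offset taken off, 333 with quantile normalization and dim genes left out, 1482 at an unadjusted p and 1.5-fold, 320 over all probesets, and 1 to 2884 with 1 array left out. For NU7441 against control, the 4917 became 2789 with the offset taken off, 10300 over all probesets (more were tested), and 868 to 7845 with 1 array left out. For knockdown against NU7441, the 1284 became 820 without the trend, 472 with the compared groups only, 325 with the offset taken off, 2777 at an unadjusted p and 1.5-fold, 1957 over all probesets, and 0 to 5101 with 1 array left out. Apart from the replicate block, the other alternatives stayed within 1.5 times.

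The 98 shared calls became 4 without the trend, 169 with quantile normalization, and 1 to 2174 with 1 array left out. The correlation of 0.649 ranged from 0.573 to 0.668 with 1 array left out, and was 0.566 and 0.600 with separate controls. Of the lists called after knockdown, 6 (3 higher, 3 lower), 3 were called with dim genes left out, and 0 by fry (7 at an unadjusted p), while 2 higher and 5 lower were called after quantile normalization and 3 and 5 with the compared groups only. Camera with an estimated correlation called 0 lists in each comparison (1, 4 and 4 at an unadjusted p for knockdown, NU7441 and knockdown against NU7441), where camera with the preset called 6, 11 and 8 and fry 0, 15 and 8. Fry's 15 lists for NU7441 were 4 higher and 11 lower, and 10 of them were also called by camera with the preset. Of its 8 lists for knockdown against NU7441, 6 were also called by camera.

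With the replicate block, the counts were 37, 4490 and 1025 genes for knockdown, NU7441 and knockdown against NU7441, 30 shared calls, and 6, 12 and 8 lists. Arrays with the same number did not deviate together (correlations of −0.005, −0.013 and −0.068), so the numbers are not treated as pairs.

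Of the named genes' alternative values, 1170 of NU7441 were the same in direction and call, 91 lost the call, 6 gained it and 1 turned direction: XRCC6 at 0.11 with median centring, which moves all genes up. For knockdown 346 were the same, 143 lost the call and 31 gained it, and for knockdown against NU7441 237 were the same and 51 lost it. HSD17B2 sat at the floor on all arrays with the offset taken off, so it has no fold there. The alternatives set out for PRKDC were not run, since it was not analysed here. Signal over background limits the dim genes: 8.51% of probesets were within 0.01 of the floor on NU7441 replicate 1.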

Other observations

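The lists here were chosen after the data were seen, and the tests on them were set before their results. The lists held 34 lysosomal, 32 spliceosome and hnRNP, 31 oxidative phosphorylation and 32 primary cilium genes, and counts are out of those measured. They were not set against random lists of matched intensity, so a shift that varies with brightness is allowed for only by quantile normalization. Most of the lysosomal genes measured rose under NU7441: of 18 members 12 passed limma's threshold, all higher, with GRN and NEU1 left out because they had drawn attention to the group. TPP1, a lysosomal peptidase, rose by 1.27 ± 0.20 on the log2 scale, the cathepsins CTSB and CTSD by 1.26 ± 0.21 and 1.17 ± 0.20, and HEXA, a hexosaminidase, by 1.11 ± 0.17 (SE, n = 2 per group). The list median was 0.79, or 1.02 relative to all genes (camera adjusted p = 1.42e-08, 2.13e-06 after quantile normalization, and adjusted p = 0.0588 with an estimated correlation). After knockdown 0 of the 18 passed singly, and the list had a camera adjusted p of 2.59e-05, higher, and 0.0658 with an estimated correlation. A lysosomal gene programme raised by NU7441 may be a hypothesis worth testing, and NU7441's action on kinases other than DNA-PKcs was not examined.

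Of 27 spliceosome and hnRNP genes 15 fell and 4 rose under NU7441. SNRPD1 fell by 2.06 ± 0.26, U2AF1 by 1.61 ± 0.18 and SNRPA1 by 1.47 ± 0.15, and the list median was −0.40, or −0.16 relative to all genes (camera adjusted p = 0.0413, 3.24e-04 after quantile normalization, and adjusted p = 0.160 with an estimated correlation). After knockdown the list had a camera adjusted p of 0.0153, lower, and an adjusted p of 0.160 with an estimated correlation. HNRNPK was the 1 member past the threshold after knockdown, at −0.73 ± 0.13, and at −0.85 ± 0.13 under NU7441. Oxidative phosphorylation (6 of 11 higher, 1 lower, adjusted p = 0.0153) and primary cilium genes (9 of 29 higher, 5 lower, adjusted p = 0.0255) were called higher as deposited but not after quantile normalization (0.185 and 0.141) or with an estimated correlation (adjusted p = 0.213 for both), so both stay open. After knockdown no gene of either list passed singly. There the oxidative phosphorylation list was called higher (adjusted p = 0.00131, 0.0117 after quantile normalization, and adjusted p = 0.160 with an estimated correlation). The cilium list was called higher as deposited (adjusted p = 0.0484) but not after quantile normalization (0.230) or with an estimated correlation (adjusted p = 0.246).

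Metallothionein genes were chosen after their values were seen, and no list test was run on them. After knockdown MT1F rose by 2.71 ± 0.31, MT2A by 0.68 ± 0.08 and MT1X by 0.67 ± 0.12, at control means of 6.49, 9.75 and 9.40 on the log2 scale. The other 6 measured were dimmer, at control means from 4.42 to 5.17. Among these, MT1M was at −0.72 ± 0.19 (adjusted p = 0.0904) and MT1G at 0.71 ± 0.21 (adjusted p = 0.112). MT1X fell by 0.77 ± 0.12 and MT1M by 1.03 ± 0.19 under NU7441.

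The lowest adjusted p after knockdown belonged to HNRNPA1P10, listed as a pseudogene, at −2.09 ± 0.07, and it was at −1.88 ± 0.07 under NU7441. RPS27, a ribosomal protein gene, was at −1.28 ± 0.09 and −0.97 ± 0.09. Both were among the brighter probesets in controls, at mean log2 values of 12.42 and 12.39, and both were chosen after their values were seen. The probes of HNRNPA1P10 may read related copies. HNRNPA1, a member of the hnRNP list, was at 0.05 ± 0.14 after knockdown and 0.36 ± 0.14 under NU7441, neither past the threshold.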
